A study of Homo sapiens with 9 samples.

How the data were processed

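Poly(A) RNA of 9 HEK293T libraries, 3 each from wild-type, VRK1-knockout and SRRM2-depleted cells, was sequenced as paired ends, per the labels' protocols. The labels call the replicates biological, name no control siRNA for the wild-type cells and do not say whether the knockout is a single clone. Per the submitters' processing notes, fastp and HISAT2 2.0.5 were run with the GRCh38 build; skipped exons were analysed with rMATS, per the series' design text. The version and settings of rMATS and the annotation are not given in the sources used here.

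The 2 deposited tables, one per perturbation against wild-type, list 63329 and 70756 skipped-exon events with raw inclusion and skipping read counts, effective lengths, inclusion levels, p-values, FDR and level differences made by the authors. Per the file headers each count cell holds the 3 libraries of a group. The authors' inclusion level is a fraction from 0 to 1, and their deposited p-value and FDR come from their rMATS run. The deposited level difference, a score from -1 to 1, is the perturbed mean minus the wild-type mean. The cells carry no replicate number, so libraries are named by their listed place. The inclusion length was the exon length plus 149 nt in every event of both tables, up to 8396 nt, and the skipping length 149 nt, which is the form used when reads inside an exon count toward inclusion, although the design text calls the counts junction reads. Long exons can therefore gain inclusion reads from retained introns.

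In some cells the 3 counts had been regrouped as if they were 1 long number. They were recovered from the digits by requiring each library's level to match the deposited one within 0.00051 and, where several splits matched, taking the one with the smallest spread among libraries. This concerned 2797 and 2846 events for the knockout and wild-type cells of the first table, and 3064 and 3275 for the depletion and wild-type cells of the other. In 1416, 1509, 1338 and 1928 of these more than 1 split matched, and 0 events were left without a match. In the chosen splits the highest library was at most 2.64 times the lowest, and in the next best split at least 9.51 times. Taking the smallest spread favours similar libraries, so fits without these events were also made. In all other cells the level computed from the counts matched the deposited one. The tables share 52359 events with the same coordinates, and wild-type counts were identical in all of them. Value columns not mapped to a group numbered 0. No pair of libraries agreed within sampling noise: the mean deviance per exon was 2.53 to 2.87 for pairs within a group, where sampling noise alone gives about 1, so no library was counted as a duplicate.

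PSI was computed per library as inclusion reads per inclusion length over that plus skipping reads per skipping length. For each target exon the event with the most reads was kept, and exons with a mean of at least 20 reads per library and at least 10 inclusion and 10 skipping reads over all libraries were tested. A quasi-likelihood count test had been planned. It was set aside once each deposited cell was seen to hold 3 counts in place of 1, and was not run, although the counts as later split per library would have allowed it. A moderated quasi-binomial F test took its place: inclusion reads out of all reads per library, with the dispersion of each exon squeezed toward a trend on depth by limma 3.58.1 in R 4.3.3, held at 1 or above, and p-values adjusted by Benjamini-Hochberg. edgeR and DESeq2 were not used. An exon was called at an adjusted p under 0.05 and a difference in mean PSI of at least 10 points. The direct contrast used the 9 libraries on shared events. The tests of single exons and of reads per gene cover the spread between these libraries and counting error only. Binomial intervals, Fisher's exact tests and permutation tests take exons or genes as independent units. They do not measure the spread between libraries, and exons of 1 gene are not independent.

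On simulated counts with 200 changed exons, changes of 0.1, 0.2 and 0.3 in PSI were called in 12.0%, 35.0% and 60.0% of cases among 14013 exons of the knockout comparison and in 4.00%, 26.0% and 40.0% among 15575 exons of the depletion comparison, with 0 unchanged exons called. With no exon changed, 5.22% and 4.85% of exons had a p under 0.05. Reads summed per gene over its events were tested with limma-voom after median-of-ratios scaling, for genes with a mean of at least 10 reads; on simulated counts 182 of 200 genes changed 2-fold were called in each comparison, with 13 unchanged genes called of 10482 in the knockout comparison and 14 of 10602 in the depletion comparison. Reads shared between events are counted repeatedly in these sums.

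Named exons followed a rule fixed before the data were examined: up to 10 largest falls and 10 largest rises per comparison with wild-type, 1 per gene, with at least 50 reads per library and libraries that do not overlap; up to 4 genes per gene list, or 6 for repair lists, by adjusted p; VRK1 and SRRM2; up to 10 exons called in both comparisons; and 6 each way in the direct contrast. No exon of VRK1 passed the filter in the knockout comparison. The lowest-p exon of SRRM2 there was at 67.4% ± 1.86 against 63.2% ± 3.45 in wild-type, and that of VRK1 in the depletion comparison at 97.2% ± 2.49 against 98.7% ± 1.86, neither past the threshold. The 11 gene lists, 5 of them on repair, damage signalling and replication, came from textbook knowledge, and each was compared with all tested genes by Fisher's exact test and with 10000 random lists matched on number of exons and depth. Exon features were compared by permutation of ranks with 100000 resamples or Fisher's exact test. Gene symbols are those of the files; 11712 of 12245 matched a symbol or synonym of the GRCh38.p14 gene table, which was used for names alone.

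Alternatives were limma on logit-transformed shares with 0.5 added to each count, robust moderation, other filters and thresholds, all listed events, PSI from raw counts, the authors' deposited FDR, 1 fit of all libraries, and each library left out in turn. Added after seeing the data were the fits without recovered cells, limma-trend for gene reads, 1 exon per gene and exons that span no intron between other listed exons for the features, 1 risen exon per gene, the gene lists' reads, and the 5 repair lists pooled. Splice site sequence and GC content were not analysed here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.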

Results

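Messenger RNA from HEK293T cells, a line derived from human embryonic kidney, was sequenced in 3 groups of 3 libraries: wild-type cells, cells in which the gene of the nuclear kinase VRK1 had been knocked out with CRISPR-Cas9, and cells harvested 48 h after transfection with 20 nM of an siRNA against SRRM2, a serine- and arginine-rich protein of the spliceosome and nuclear speckles. The series title links VRK1 to SRRM2 and to the splicing of repair factors, so the comparisons ask which exons were included differently in each perturbed group, whether the same exons changed in both, and whether repair genes were among them. The measurement is the percent spliced in (PSI), the share of transcripts that include a given internal exon, from reads supporting inclusion or skipping. Reads summed over the listed events came to between 15886775 and 17379104 per library in the table of the knockout comparison and between 17659140 and 19822054 in that of the depletion comparison, and a read can be counted in more than one event. Exon positions are on GRCh38, and values are means ± SD over 3 libraries.

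The targeted genes were measured first, in RPM, the reads at a gene's events over library sizes set by median-of-ratios scaling. VRK1 averaged 23.3 ± 0.518 RPM in the knockout libraries and 67.6 ± 7.83 in wild-type (n = 3 each), a 2.88-fold lower level with a log2 fold change of -1.52 (SE 0.11, limma-voom adjusted p = 3.67e-06). SRRM2 averaged 102 ± 10.1 RPM after depletion and 214 ± 7.35 in wild-type, a 2.10-fold lower level with a log2 fold change of -1.07 (SE 0.07, limma-voom adjusted p = 4.52e-07). In both cases every perturbed library lay below every wild-type library. SRRM2 reads in the knockout differed from wild-type by a log2 fold change of -0.01 (SE 0.05, limma-voom adjusted p = 0.944), and VRK1 reads after SRRM2 depletion by less than 0.01 (SE 0.09, limma-voom adjusted p = 0.976).

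**Figure D1:**
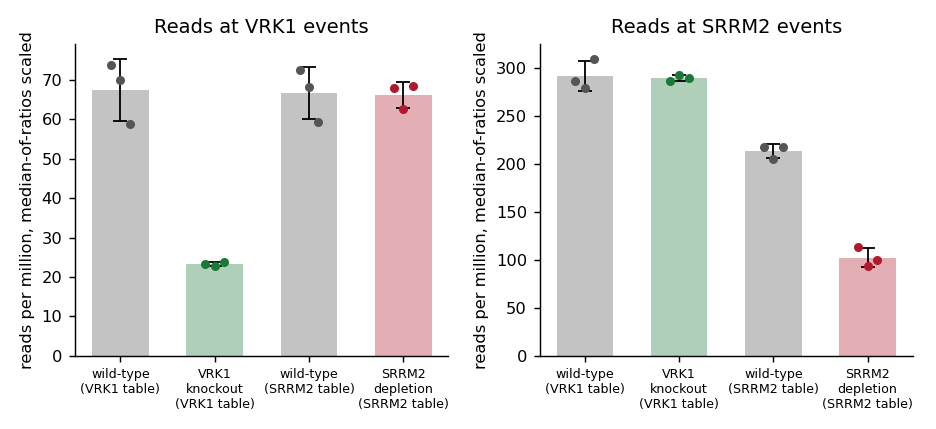
RPM at the events of VRK1 (left) and of SRRM2 (right) for each group of each deposited table. Bars are means, error bars SD, and points the 3 libraries; VRK1 averaged 23.3 RPM in the knockout against 67.6 in wild-type, and SRRM2 102 after depletion against 214.

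VRK1 knockout had few called exons at the thresholds used. An exon of SCMH1 (chromosome 1, 41033983 to 41034048), which encodes a Polycomb group protein, fell from 100% ± 0 in wild-type to 57.6% ± 11.1 in the knockout, and one of KAT7 (chromosome 17, 49809119 to 49809208), a histone acetyltransferase of the MYST family, from 100% ± 0 to 79.3% ± 5.49 (n = 3 each). An exon of KDM3B (chromosome 5, 138431425 to 138431559), a demethylase of histone H3 lysine 9, fell from 95.2% ± 2.18 to 75.7% ± 1.96. The quasi-binomial adjusted p was 0.000823 for SCMH1 and KDM3B and 0.000929 for KAT7. Of 14013 exons tested in 6419 genes, 8 passed an adjusted p of 0.05 with a PSI difference of at least 10 points, 6 lower and 2 higher in the knockout. On the same exons the authors' deposited FDR gave 28, of which 13 were lower and 15 higher, and 6 of the 28 were among the 8.

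The other falls were in C19orf12 (chromosome 19, 29705274 to 29705394), from 100% ± 0 to 44.6% ± 5.18 over a mean of 43.3 reads per library, in CBS (chromosome 21, 43067778 to 43067960), the cystathionine beta-synthase gene, from 41.7% ± 4.90 to 18.3% ± 17.0, and in MAN2C1 (chromosome 15, 75365601 to 75365698), an alpha-mannosidase gene, from 24.5% ± 5.86 to 3.38% ± 4.89. FAM171A1 (chromosome 10, 15248639 to 15248815) rose from 73.3% ± 1.98 to 98.1% ± 3.27. The remaining rise, in MAGEA2, was looked at after its values were seen and is uncertain, because the gene has near-identical copies and its exon averaged 24.0 reads per library. At an unadjusted p under 0.05 there were 894 exons where 701 are expected by chance. Without the third wild-type library 1 exon was called, and without the second 4. KDM3B was the single named exon called with each library left out in turn, although not by limma on logit-transformed shares, which called 4 exons, and SCMH1 and KAT7 were lost without the third wild-type library alone. C19orf12 was called in 3 of 6 such fits, MAN2C1 and FAM171A1 in 2 and CBS in 1. The CBS exon did not pass 0.05 by the authors' deposited FDR (0.0789). Of the 11 gene lists, chromatin modifiers had 1 gene with a called exon of 82 tested, KAT7 (Fisher's exact test adjusted p = 1.00; 1 exon adjusted over the list alone). That list holds neither KDM3B nor SCMH1, so their called exons do not enter its count. The quasi-binomial test called 0 exons in each of the other lists, where 1 to 18 exons had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Such exons made up 3.4% to 12.2% of a list's exons, against 6.38% of all tested exons. The highest shares were in SR proteins (12.2%) and hnRNP regulators (11.2%).

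None of the 145 tested genes on the 5 lists of repair, damage signalling and replication factors had a called exon in VRK1 knockout, over 361 exons with a median of 139 reads per library, and 0 exons passed when adjusted over these lists alone. Of these exons 22 had an unadjusted quasi-binomial p under 0.05 and limma on logit-transformed shares called 0. The lowest p belonged to ORC2, a subunit of the origin recognition complex, at 86.2% ± 7.49 in the knockout and 98.5% ± 2.69 in wild-type, and to DNA polymerase beta, POLB, at 1.65% ± 0.315 and 8.93% ± 4.71 (quasi-binomial adjusted p = 0.518 for both). At this depth 35.0% of simulated changes of 0.2 in PSI were called in this comparison, so smaller or shallower changes would mostly have been missed. The authors' deposited table passes an FDR of 0.05 with a difference of 0.1 or more at events in 4 genes of these lists: ATM, DCLRE1C, L3MBTL1 and PALB2, each over fewer than 20 reads per library.

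Many exons had lower inclusion after SRRM2 depletion than in wild-type cells. No control siRNA is labelled, so transfection itself and loss of SRRM2 cannot be told apart. The largest falls by the rule for named exons were in the homeobox gene SIX5 (chromosome 19, 45766350 to 45767155), from 84.7% ± 7.56 in wild-type to 28.2% ± 8.14 after depletion, in DDX3X (chromosome X, 41337691 to 41339083), an RNA helicase gene, from 91.0% ± 10.8 to 42.1% ± 3.14, and in the kinase gene MAP3K10 (chromosome 19, 40213517 to 40214221), from 98.1% ± 3.22 to 50.8% ± 10.3 (n = 3 each). FAM189B (chromosome 1, 155250276 to 155250929) fell from 95.8% ± 7.24 to 52.0% ± 3.97 and PRR14 (chromosome 16, 30654629 to 30655214) from 94.1% ± 6.41 to 53.6% ± 1.70. The exons of SIX5, DDX3X, MAP3K10, FAM189B and PRR14 were 586 to 1393 nt long, against a median of 105 nt for fallen exons. Reads inside an exon count toward inclusion, which matters more in such long exons. Of 15575 exons tested in 6807 genes, 298 in 239 genes were called, of which 281 fell and 17 rose. The falls made up 94.3% of the calls (exact 95% binomial interval 91.0 to 96.6).

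The remaining largest falls were in SPOUT1, RCHY1, STAG3L5P-PVRIG2P-PILRB, ZNF227 and ADGRE5, with differences between -45.2 and -40.4 points; STAG3L5P-PVRIG2P-PILRB is a read-through of neighbouring genes, so its reads may be shared. The DDX3X exon spans an intron between other listed exons of the gene, and reads inside that intron count toward inclusion. The named rises were smaller. ENOSF1 rose from 66.5% ± 5.57 to 95.9% ± 7.03, LRIF1, which encodes a nuclear receptor-interacting factor, from 44.4% ± 7.17 to 66.3% ± 3.43, ZNF346 from 85.2% ± 4.10 to 100% ± 0, and RABEPK, DEPDC1, TM7SF3, TBC1D2B and MTMR1 by between 10.5 and 13.9 points. Among all tested exons, called or not, 22.8% had libraries that did not overlap between the groups, against 10% by chance for 3 against 3.

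Without the first, the second or the third wild-type library 194, 171 and 189 exons were called, and without the first, the second or the third depleted library 189, 180 and 221. Of the 15575 tested exons, the authors' deposited table has 280 past an FDR of 0.05 with a difference of 0.1 or more, and 217 of these were among the 298. Limma on logit-transformed shares called 97, of which 78 were among the 298 in the same direction. The falls of SIX5, DDX3X, MAP3K10, FAM189B, PRR14 and SPOUT1 and the rise of ZNF346 were called in 6 of the 6 fits that leave out a library, but limma called neither DDX3X, FAM189B, PRR14 nor SPOUT1. It lost 30 of the 39 exons named for the depletion here and below. The rises of LRIF1, RABEPK and TM7SF3 and the falls of ADGRE5 and STAG3L5P-PVRIG2P-PILRB were called in 1 of 6. In between, ENOSF1, TBC1D2B and RCHY1 were called in 2 of 6, DEPDC1 and MTMR1 in 3 and ZNF227 in 5. The rises of LRIF1, DEPDC1, TM7SF3 and MTMR1 did not pass 0.05 by the authors' deposited FDR (0.066, 0.322, 0.501 and 0.122). Over all tested exons the median difference was -0.00961 in PSI, and 65.8% of exons were lower after depletion.

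**Figure D2:**
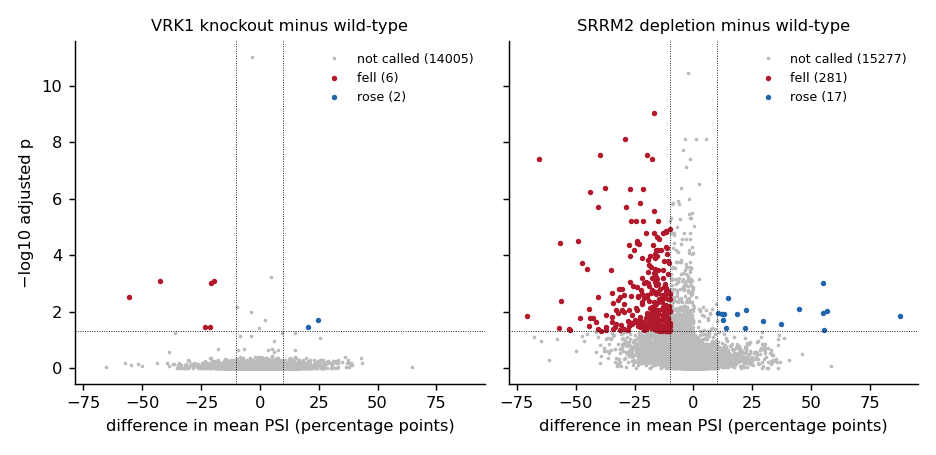
Difference in mean PSI between perturbed and wild-type libraries, in percentage points, against −log10 of the quasi-binomial adjusted p for each tested exon in VRK1 knockout (left) and SRRM2 depletion (right). Dotted lines mark the thresholds; 6 exons fell and 2 rose in the knockout, against 281 and 17 in the depletion.

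**Figure D3:**
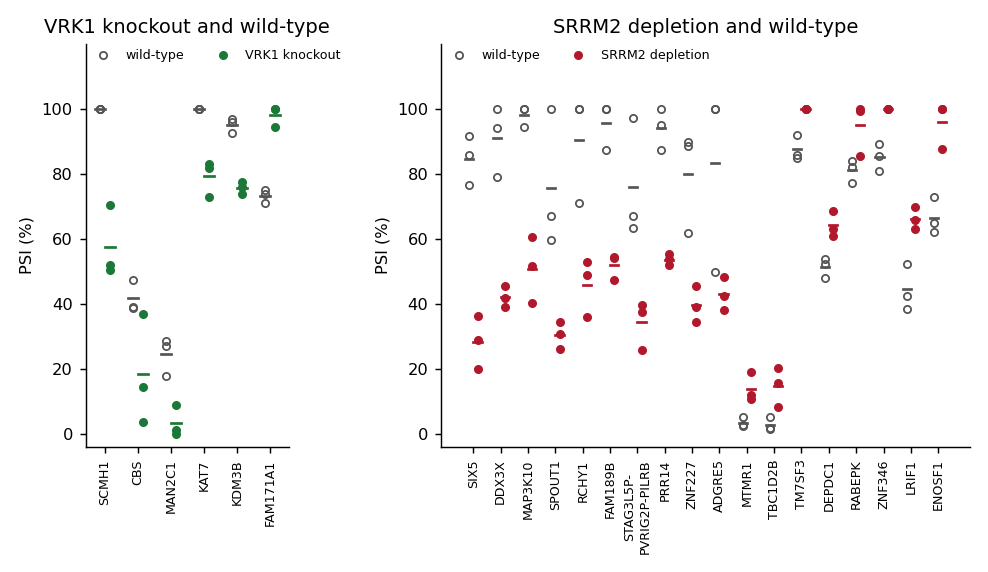
PSI in percent in each of 3 wild-type libraries (open circles) and 3 perturbed libraries (filled circles) for the named exons with the largest falls and rises, VRK1 knockout on the left and SRRM2 depletion on the right. Horizontal ticks are means; SIX5 fell from 84.7% to 28.2% after SRRM2 depletion.

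Splicing regulators were among the genes with lower inclusion after SRRM2 depletion. Of 51 tested genes for hnRNP and other RNA-binding regulators, 5 had a called exon and each of their 6 called exons fell. RBM23 fell from 88.0% ± 2.24 to 63.6% ± 0.583 (chromosome 14, 22905606 to 22905659), RBM5 from 81.7% ± 4.46 to 63.4% ± 0.831 (chromosome 3, 50110379 to 50110463), HNRNPH1 from 79.0% ± 1.46 to 64.4% ± 3.04 (chromosome 5, 179619269 to 179619360) and PTBP1, the polypyrimidine tract-binding repressor of exon inclusion, from 63.2% ± 1.16 to 51.3% ± 1.5 (chromosome 19, 805492 to 805569). The count exceeded the 1.79 genes expected by chance with an odds ratio of 3.03 (Fisher's exact test p = 0.0324), but not after adjustment over 11 lists (adjusted p = 0.337), and 17.8% of random lists matched on exon number and depth held as many. Adjusted over the list alone, 8 exons were called. Limma on logit-transformed shares called none of the exons named for RBM23, RBM5, HNRNPH1 and PTBP1.

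Among 64 tested core spliceosome genes, 2 had called exons, all 5 of which fell: SF1, the branch point-binding protein, from 49.6% ± 4.44 to 34.4% ± 1.12 (chromosome 11, 64765951 to 64766155) and PRPF39 from 48.1% ± 4.80 to 30.8% ± 4.23. The PRPF39 exon spans an intron between other listed exons of the gene and was called in 2 of 6 fits that leave out a library. Among 31 SR and SR-related genes 2 were called, SCAF4 from 100% ± 0 to 85.9% ± 7.46 and SRRM2 itself, whose exon on chromosome 16 (2758985 to 2759047) fell from 99.0% ± 0.883 to 85.9% ± 1.01. SRRM2 is the gene that the siRNA targets, so its PSI need not reflect a change in splicing alone. Chromatin modifiers had 6 genes with called exons of 80 tested, all 10 exons falling, among them SETD5 from 99.7% ± 0.554 to 80.5% ± 5.35, INO80E from 50.1% ± 4.55 to 30.7% ± 2.05, KDM2B from 99.4% ± 0.561 to 84.5% ± 2.62 and KDM6A from 100% ± 0 to 90% ± 2.6. Mitosis and centrosome genes had 4 of 77, all 7 exons falling, including the polo-like kinase PLK4 from 100% ± 0 to 70.6% ± 14.0, the kinesin KIF23 from 95.9% ± 7.12 to 64.0% ± 5.76, CKAP2 from 96.5% ± 2.40 to 82.9% ± 6.62 and SASS6 from 99.1% ± 0.837 to 87.4% ± 10.2. Of 29 apoptosis genes, BAX fell from 97.6% ± 3.74 to 84.8% ± 3.97 and DAP3 from 98.7% ± 1.15 to 88.1% ± 1.48. Adjusted over the list alone, the calls numbered 8 exons for the core spliceosome, 2 for SR proteins, 10 for chromatin, 6 for mitosis and 2 for apoptosis. No list differed from all tested genes after adjustment (Fisher's exact test adjusted p from 0.337 to 1.00). The SASS6 call was lost whichever of the 6 libraries was left out, and that of SCAF4 in 5 of 6 such fits. RBM5, KDM6A and PLK4 were called in 4 of 6 and KIF23, CKAP2 and DAP3 in 5. Of the exons named in this paragraph, limma called those of SCAF4, SETD5, KDM2B, KDM6A and PLK4 and no other.

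Repair and replication genes carried 1 called exon after SRRM2 depletion. ORC1, the largest subunit of the origin recognition complex, fell from 87.4% ± 0.666 to 67.5% ± 4.73 at the exon on chromosome 1 from 52383830 to 52383937 (quasi-binomial adjusted p = 0.0139), a call kept without the third depleted library and lost without any other of the 6. It was the single gene called among 36 translesion and replication fork genes, and there was none among 44 genes of homologous recombination and Fanconi anaemia, 13 of end joining, 35 of excision and mismatch repair, or 34 of damage signalling. In these 4 lists 16 of 120, 11 of 32, 10 of 90 and 15 of 75 exons had an unadjusted p under 0.05. These shares were 13.3%, 34.4%, 11.1% and 20.0%, against 18.9% of all tested exons. Limma on logit-transformed shares called none in these lists. Adjusted over the list alone 0, 4, 0 and 0 exons were called, and for translesion and replication genes that number was 2. Across all 5 lists together, a grouping chosen after the data were seen, 1 of 161 tested genes had a called exon where 5.65 were expected (Fisher's exact test p = 0.0466, unadjusted). That count of 1 was not stable. It was 4 with robust moderation (APTX, FANCA, ORC1 and TONSL), 3 with all listed events and 8 with no PSI threshold. It was 6 by the deposited FDR over all listed events and 0 with limma on logit PSI.

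Smaller differences passed the test without reaching 10 points. RPA2, a subunit of the single-stranded DNA-binding complex RPA, was at 93.6% ± 0.593 after depletion and 98.2% ± 0.358 in wild-type (quasi-binomial adjusted p = 0.000444), ORC6 at 91.0% ± 1.63 and 99.3% ± 1.2 (adjusted p = 0.00376), and PRKDC, the catalytic subunit of DNA-dependent protein kinase, at 98.3% ± 0.121 and 100% ± 0 (adjusted p = 0.0155). These were named after their values were seen, and none of these exons passed 0.05 by the authors' deposited FDR (0.447 for ORC6, higher for RPA2 and PRKDC). With all listed events tested in place of 1 per exon, BRCC3 and RAD51C were called beside ORC1. The authors' deposited table passes an FDR of 0.05 with a difference of 0.1 or more in 6 genes of these lists, RAD51C, FANCI, BRCC3, DCLRE1C, CDKN1A and ORC1.

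SRRM2 depletion and VRK1 knockout were also compared directly, through the events that both deposited tables list. The labels give an siRNA for the depleted cells alone, so transfection itself is part of this contrast too. MAP3K10 was at 50.8% ± 10.3 in the depletion and 100% ± 0 in the knockout, SIX5 at 28.2% ± 8.14 and 82.9% ± 10.3, FAM189B at 52.0% ± 3.97 and 93.8% ± 2.07, SPOUT1 at 30.3% ± 4.27 and 75.8% ± 12.7, RAB11FIP5 at 32.2% ± 3.70 and 78.2% ± 19.3, and PLSCR3 at 23.5% ± 22.2 and 67.5% ± 21.7 (n = 3 each). Inclusion was higher in the depletion for OSBPL8, RABL2B, LRIF1, ERCC8, CLK1 and KDM3B, by between 18.4 and 40.2 points. The exons of RAB11FIP5, LRIF1 and ERCC8 were long, at 2013, 1528 and 1607 nt, and reads inside them count toward inclusion. For KDM3B the depletion libraries were at 94.2% ± 2.43 against 75.7% ± 1.96 in the knockout, and wild-type was at 95.2% ± 2.18. Of 18390 exons tested, 448 differed, 422 lower and 26 higher in the depletion. Limma on logit-transformed shares called 63 of the 18390, 62 lower and 1 higher, and of the 12 named ones it lost 10, all but MAP3K10 and SIX5. Without the third knockout library 278 exons were called. RABL2B, which has a close paralog, was called in 1 of 9 fits without 1 library, CLK1 in 3, PLSCR3 in 4 and OSBPL8 in 6. Among the gene lists, 7 of 51 hnRNP and other RNA-binding regulators, 7 of 65 core spliceosome genes and 9 of 86 chromatin modifiers had a called exon (Fisher's exact test adjusted p = 0.138, 0.154 and 0.154), and adjusted over the list alone 11, 12 and 16 exons were called; no list passed the threshold.

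Repair genes differed between the perturbations at 9 exons in 9 of 164 tested genes, where 8.18 genes were expected (Fisher's exact test p = 0.716). Adjusted over the repair lists alone, 6 exons were called. ERCC8, a transcription-coupled repair factor, was at 33.0% ± 11 in the depletion and 11.1% ± 1.04 in the knockout (quasi-binomial adjusted p = 0.000394). Among the lower ones were RIF1 at 59.5% ± 1.52 against 81.4% ± 7.58, the checkpoint kinase gene CHEK2 at 72.4% ± 3.27 against 89.1% ± 1.31, POLQ at 64.6% ± 6.92 against 94.1% ± 6.17, TONSL at 76.1% ± 7.27 against 90.7% ± 3.21 and BRCA2 at 69.1% ± 3.83 against 99.0% ± 1.68, the last over a mean of 34.3 reads per library. These genes were named after their values were seen, and apart from ORC1 none of the 9 was called against wild-type in either comparison. Wild-type was at 20.2% ± 2.49 for the ERCC8 exon and 78.1% ± 6.02 for the CHEK2 exon, between the depletion and the knockout. Part of each of these differences in means thus lay between the knockout and wild-type. That part did not pass the test for either exon (quasi-binomial adjusted p = 0.629 for ERCC8 and 0.719 for CHEK2).

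SCMH1 and C19orf12 fell in both comparisons. SCMH1 was at 74.0% ± 22.8 after SRRM2 depletion and 57.6% ± 11.1 in VRK1 knockout against 100% ± 0 in wild-type, and C19orf12 at 68.9% ± 32.8 and 44.6% ± 5.18 against 100% ± 0. Of 12455 exons tested in both, 6 fell in the knockout and 223 in the depletion, so independent lists would share 0.107, and 2 were shared; no rise was shared. Both comparisons use the same wild-type libraries, and the overlap was 1 without the first wild-type library and 0 without the second or the third. In the depletion comparison the libraries of both exons overlapped those of wild-type, and each call held in 1 of the fits that leave out a library. KAT7 was at 91.6% ± 6.49 in the depletion, a difference of -8.37 points. It passed the adjusted p (quasi-binomial adjusted p = 0.019) but not the 10-point threshold. The other exons fallen in the knockout, in CBS, MAN2C1 and KDM3B, differed by -17.7, -6.87 and -1.04 points in the depletion (quasi-binomial adjusted p = 0.426, 0.673 and 0.877). FAM171A1, which rose in the knockout, differed by 1.06 points (0.946). Shared wild-type libraries can push such differences to the same side.

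PSI differences of the 2 comparisons correlated across 12391 exons with a Pearson r of 0.371 and a Spearman rho of 0.319, while unchanged groups simulated against shared wild-type libraries gave means of 0.492 and 0.434; exons are not independent replicates. The covariance was 0.00153, above each of 100 simulated draws (mean 0.00136, range 0.00124 to 0.00146). Computed from the spread of the wild-type libraries it was 0.00151. The differences had the same sign in 61.8% of exons and in 66.4% of simulated ones. The simulated groups hold no effect of SRRM2 depletion, which can lower the correlation and the share of equal signs with or without a shared effect. A correlation and a share below the simulated ones therefore do not decide whether an effect is shared. The wild-type group has too few libraries to be split into separate sets of at least 2, so part of any overlap may come from the shared controls.

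Exons that fell after SRRM2 depletion lay between short introns. The median upstream intron was 671 nt for the 281 fallen exons and 1729 nt for the 15277 exons not called, and the median downstream intron 742 nt against 1645 nt (permutation test of ranks, two-sided, p = 1e-05 for both, the smallest the permutations can give, adjusted p = 6e-05 over 24 tests). Exons not called but drawn to match the fallen ones in wild-type PSI and depth had median upstream introns of 1755 nt (95% of draws 1415 to 2192) and downstream introns of 1609 nt (1293 to 1997). Fallen exons had a median length of 105 nt against 115 nt (adjusted p = 0.229), and 47.0% against 42.5% had a length divisible by 3 (Fisher's exact test adjusted p = 0.266). The 17 risen exons had a median length of 176 nt (adjusted p = 0.0446 against exons not called). However, 4 of them were neighbouring or overlapping exons of BCS1L, a gene named after its values were seen. With 1 risen exon per gene, also chosen after the data were seen, the median of 14 exons was 161.5 nt (permutation test, unadjusted p = 0.0775, against 0.013 for the 17). An intron between other listed exons lay inside 11 of the fallen exons, 3.92%, against 0.982% of those not called (Fisher's exact test adjusted p = 0.000667). In VRK1 knockout, with 6 fallen and 2 risen exons, no feature differed after adjustment (adjusted p = 1.00 throughout).

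**Figure D4:**
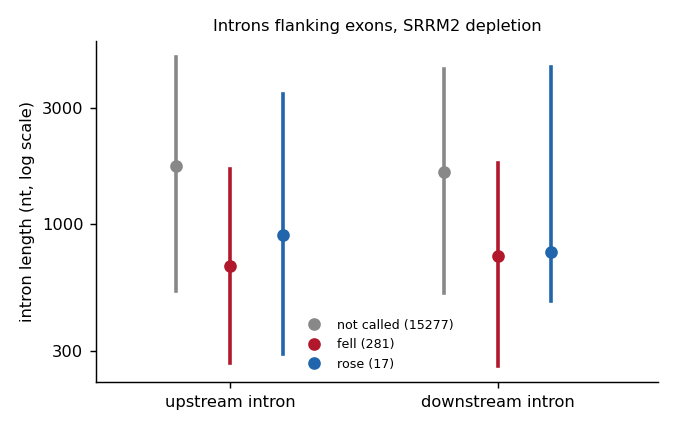
Length of the introns upstream and downstream of exons that fell, rose or were not called in SRRM2 depletion, in nucleotides on a log scale. Points are medians and lines run from the lower to the upper quartile; fallen exons had medians of 671 and 742 nt against 1729 and 1645 nt for exons not called.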

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

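The fits without recovered cells, with 1 exon or 1 risen exon per gene and without exons that span an intron were chosen after the data were seen. The VRK1 count of 8 became 4 with limma on logit-transformed shares, with no filter or at an adjusted p under 0.01, 14 with no PSI threshold, 28 with the deposited rMATS FDR on the same exons (13 fell, 15 rose) and 113 over all listed events, and 1 to 10 with a library left out. The SRRM2 count of 298 became 97 with limma, 166 with no filter, 733, 475 and 112 with no PSI threshold, 0.05 and 0.2, 154 at an adjusted p under 0.01, 565 with the deposited FDR over all listed events, and 171 to 221 with a library left out; the direct count of 448 became 63, 251, 1006, 685, 167 and 248 in that order, and 278 to 448 with a library left out. Falls were the majority in every setting of both: 96.8%, 90.4%, 90.4% and 80.7% at an adjusted p under 0.01, with raw-count PSI, with the deposited FDR on the same exons and over all events for SRRM2, and 98.4%, 96.8% and 89.5% with limma, no filter and raw-count PSI for the direct contrast. Shared exons numbered 4 with no PSI threshold, 1 at a minimum of 50 reads, and 0 to 1 with a wild-type library left out. Gene lists past the threshold numbered 2 with no PSI threshold in the depletion and in the direct contrast (hnRNP regulators and core spliceosome), and 1, hnRNP regulators, in the direct contrast without recovered cells. Exon features were judged here by p not adjusted over the 24 tests. By the permutation test (p = 0.105 for the reported median of 105 nt), the length of fallen exons passed 0.05 at a PSI threshold of 0.05 (98 nt), with 1 exon per gene (99 nt), without exons spanning an intron (100 nt, p = 0.0145) and at a minimum of 50 reads (p = 0.0436, with the median still 105 nt). So did the 49.0% with a length divisible by 3 at a threshold of 0.05. The greater length of risen exons no longer did so with 1 risen exon per gene (161.5 nt, 14 exons); 4 of the 17 came from 1 gene. The short flanking introns kept their side of the threshold in each setting, as did the lower VRK1 and SRRM2 reads. Named calls were lost in 25 of 97, 145 of 539 and 39 of 191 values for the knockout, the depletion and the direct contrast, and none reversed; 1 of 7, 16 of 39 and 8 of 12 named exons were called with every library left out in turn. Leaving out a library leaves 5 or 8 libraries in the fit; the cause of the other shifts was not tested. Neither the planned quasi-likelihood count fits nor DESeq2 fits were run, although the counts as split per library would have allowed them. No paired analysis was possible because the places in a cell carry no replicate numbers. At this depth 35.0% and 26.0% of simulated PSI changes of 0.2 were called in the knockout and the depletion comparison, so a missing call does not show that an exon was unchanged.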

Other observations

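The tests of power, of the knockout's label and of the shared wild-type libraries, and the gene list counts of reads, were chosen after the results were seen. Spliceosome genes had more reads after SRRM2 depletion. Of 75 core spliceosome genes 33 rose and 4 fell in reads summed over their events, with a median log2 fold change of 0.19, while 1426 of all 10602 genes rose and 1293 fell (Fisher's exact test adjusted p = 1.84e-09 for the rises). SNRPC, a U1 snRNP subunit, rose by 0.49 (SE 0.05), PUF60 by 0.48 (SE 0.05) and the kinase gene CLK1 by 0.61 (SE 0.08), while XAB2 had a log2 fold change of -0.93 (SE 0.10). Of 35 SR and SR-related genes 15 rose (Fisher's exact test adjusted p = 0.000201), among them SRRM1 by 0.59 (SE 0.06), TRA2A by 0.37 (SE 0.05) and SON by 0.30 (SE 0.04), and SRRM2 fell. Scaled to library totals, 20 core spliceosome and 9 SR genes rose and 8 and 3 fell, with the deepest event of each gene 26 and 10, and with a library left out 25 to 31 and 10 to 14. The rises and falls of all genes at these settings are not given here, so the excess of rises over all genes is shown for the main setting alone. Each log2 fold change comes from limma-voom on 3 against 3 libraries.

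Chromatin modifiers had 21 falls among 94 genes (Fisher's exact test adjusted p = 0.0452), including SMARCC2 at -0.44 (SE 0.07) and DNMT1 at -0.27 (SE 0.04). With the deepest event of each gene 10 fell, with library totals 31, and with a library left out 12 to 22. Of 47 genes in excision and mismatch repair 0 fell in reads by limma-voom (Fisher's exact test adjusted p = 0.0373), but 5 fell with library totals and 1 without the first or the third wild-type library. In VRK1 knockout, 93 of 10482 genes rose and 123 fell in reads, and 4 of 53 hnRNP regulators fell, TIAL1, RBM6, HNRNPAB and KHDRBS3 (adjusted p = 0.0373). That last count was 0 with the deepest event of each gene, 2 without the first wild-type library, and 0 without the second wild-type library or any of the knockout libraries.

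Called exons of SRRM2 depletion mostly fell, 281 against 17. The real grouping gave 298 called exons and the highest other split of the 6 libraries 2, with 1 of 10 splits as large, too few splits for a share under 0.05. More room to fall than to rise is argued against as the whole cause, since among called exons with wild-type PSI between 35% and 65%, 30 of 37 fell (81.1%, exact 95% binomial interval 64.8 to 92.0). Reads inside exons that span an intron between other listed exons are argued against too, as 94.7% (91.3 to 97.1) of called exons of at most 300 nt without such an intron fell. Libraries labelled with a control siRNA numbered 0, so transfection itself and loss of SRRM2 cannot be told apart, and a role of SRRM2 in the inclusion of exons between short introns may be offered as a hypothesis and no more.

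Few exons were called in VRK1 knockout. The real grouping gave 8 and the highest other split 7, with 1 of 10 splits as large, too few for a share under 0.05. A mislabelled or unedited line is argued against by VRK1 reads, whose highest knockout library was at 40.6% of the lowest wild-type library. Lower power than in the SRRM2 comparison is argued against as the whole cause. On the 12455 exons tested in both comparisons the fitted dispersion was 1.05 times as high in the knockout comparison (median ratio), at 1.05 times the reads. With each exon's F rescaled to the dispersion, reads and degrees of freedom of the knockout fit, 278 of these exons (2.23%, exact 95% binomial interval 1.98 to 2.51) were called in the depletion. In the knockout 7 were called (0.0562%, 0.0226 to 0.116). Remaining VRK1 protein was not measured here, so residual activity may be a candidate explanation that stays open, as does a small effect of VRK1 on exon inclusion. For the direct contrast the real grouping gave 448 called exons and the highest other split 7, with 1 of 10 splits as large.

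The PSI differences of both comparisons correlated across exons. Their covariance was 1.01 times the one computed from the spread of the shared wild-type libraries, which is what shared controls alone would give. At 0.00153 it was, however, above the highest of 100 simulated draws of unchanged groups (0.00146). These measures differ, so whether shared controls are the whole source of the correlation stays open. Exons with an unadjusted p under 0.05 in both comparisons and the same sign numbered 187, against 75 to 128 in 100 simulated draws of unchanged groups; those draws leave out the effects of SRRM2 depletion, so a shared effect on some exons stays open.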
